A study of Sus scrofa with 4 samples.

How the data were processed

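The samples were 4-cell porcine embryos in 2 groups of 2 libraries. The sample titles read control and SiTF, and SiTF was taken as TFAP2C knockdown from the series design. The groups are called labelled control and labelled TFAP2C knockdown. Per the labels' protocols, small interfering RNA was injected into the cytoplasm, RNA was extracted with an RNeasy Mini Plus kit and libraries were made with a SMARTer mRNA-seq kit, which amplifies cDNA from little input. Amplification makes abundance of rare transcripts noisy. Per the submitters' processing notes, cutadapt, Bowtie2 2.3.5, StringTie 2.1.7 and the pig assembly Sscrofa11.1 were used; the role of each tool, the annotation release, filters and counting settings are not given in the sources used here. Bowtie2 does not split reads across introns, so if it aligned reads to the genome, reads over exon junctions would be lost, but the notes do not say to what it aligned.

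The deposited table has 35395 rows, each a transcript, with a coverage, an FPKM and a TPM value for each of the 4 libraries and no pooling, per the file headers. Deposited coverage is the mean read depth per base of a transcript and is not scaled for depth, as StringTie names it. Deposited FPKM is scaled by the authors for transcript length and library size, and its sum differs between libraries, from 489479 to 657450. Deposited TPM is scaled by the authors so that each library has the same sum, which was checked on the file (the sums lay between 999979 and 1000021). No read counts were used, since the table gives none, and the values are not whole multiples of a step, so tests were run on log2 FPKM. Coverage divided by FPKM was a single constant per library, within a relative tolerance of 2e-06 and the rounding of the printed decimals. If FPKM was computed from coverage as StringTie does, that constant is the aligned bases in gigabases, 6.69, 7.03, 6.07 and 8.83 for labelled controls 1 and 2 and labelled knockdowns 1 and 2. The same check found that 1 row, that of TFAP2C, does not carry the constants of its own libraries. With 4 libraries there are 2 residual degrees of freedom, and depth was not compared with the spread between libraries. Values of exactly 0 may be failed estimates, since housekeeping genes are also at 0 (RPL3 in 3 libraries), so such genes are said to be listed at 0, with each library's value.

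Rows were matched to a table of RefSeq genes of Sscrofa11.1, which is the build the submitters name, and gene coordinates are those of that table, 1-based and spanning the whole gene. Of the rows, 32816 were named by their transcript accession and 4 more by another version of it. Another 2305 had a gene symbol as ID, 246 took the name in the file and 24 had none. In the name column, 129 rows held a date in place of a MARCH or SEPT gene and 887 rows a 0. FPKM was summed over the transcripts of a gene, giving 25560 gene names, 5960 of them with more than 1 transcript row. Transcripts with shared exons, paralogs and processed copies can split reads in ways that the table does not show.

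Genes with a mean of at least 1 FPKM over the 4 libraries were tested, 9850 in all. Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend) on log2(FPKM + 1), with group as the only term, and p-values, two-sided, were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low levels. The design had foreseen a count test in case the table held counts; as it does not, the test planned for FPKM was used. Gene lists were tested with camera from limma, with the preset inter-gene correlation of 0.01, on the 24 of 26 lists with at least 5 tested members, adjusted over the lists. The lists past the threshold are also given with an estimated correlation, and counts of members are given over all genes and adjusted over the list alone. The estimated form tests on the 2 residual degrees of freedom, so a call lost with it does not measure correlation alone. For apoptosis the estimated correlation was 0.0015, under the preset, yet the unadjusted p went from 0.061 to 0.19 (camera). The 26 lists are the TFAP2 family, DNA methylation, H3K4, H3K9 and H4K20, and H3K27 methylation, histone acetylation, histone variants, autophagy, DNA damage, apoptosis, oxidative stress, pluripotency, trophectoderm, genome activation, oocyte transcripts, maternal mRNA decay, cell cycle, imprinted genes, heat shock, interferon response, cumulus markers, blood cell and sperm markers, oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins and the proteasome. The lists, the design and the rule for named genes were fixed before the data were examined. The rule names TFAP2C, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold that have a symbol, a value above 0 in every library, a mean of at least 5 FPKM in the higher group and no overlap between the groups (267 rises and 100 falls were eligible), 11 fixed regulators, and up to 4 members of each list with the smallest p, of which the text gives only some. Some items that the rule names are not reported here.

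The fit was tested on simulated data for this comparison, 10 data sets of 9850 genes with 200 changed and 2 libraries a group. It recovered 0.147% of genes changed by 1 on the log2 scale, 26.1% of those changed by 2 and 94.1% of those changed by 4, and 3.64% of its calls were unchanged genes. A list shifted by -0.7 was called in 10 of 10 data sets, and 1 other list was called over 20 data sets. The simulated genes were drawn independently, while the 5 called lists had estimated correlations of 0.036 to 0.66. The simulation therefore does not give the rate of false calls for lists with correlated members. In the data 1378 genes were higher and 1371 lower at an unadjusted p under 0.05 (limma), so recovery may differ from that with 200 changed. Changes of 2-fold are therefore mostly missed with 2 libraries a group.

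The alternatives tried were the replicate number as a block, leaving out each library, a pseudocount of 0.1, no filter on low values, a minimum mean of 5 FPKM, median-ratio scaling, quantile normalization, limma without a trend, an added fold threshold of 2, an estimated correlation and fry for the lists. Added after the data were seen were TPM in place of FPKM, genes above 0 in all 4 libraries, transcript rows in place of gene sums, and the TFAP2C values placed by their constants. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.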

Results

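RNA was sequenced from 4-cell embryos of the pig (Sus scrofa), the stage at which the porcine embryo begins its main wave of transcription from its own genome while RNA stored in the oocyte is still present. Embryos had received a small interfering RNA by injection into the cytoplasm, either a control or one against TFAP2C (AP-2 gamma), a transcription factor best known from the trophectoderm and the germ line. There were 2 libraries labelled control and 2 libraries labelled knockdown, and the labels give neither the number of embryos in a library nor whether the libraries of a group came from separate embryo pools. P-values therefore measure only the spread between these 4 libraries, which may be technical. The deposited values imply 6.69 and 7.03 aligned gigabases in labelled controls 1 and 2 and 6.07 and 8.83 in labelled knockdowns 1 and 2. Between 9238 and 9917 genes reached 1 FPKM (fragments scaled to transcript length and to the fragments of the library) in a library. Transcripts encoded by the mitochondrial genome made up 21.7% and 29.1% of all transcripts in labelled controls 1 and 2. They made up 45.8% and 31.9% in labelled knockdowns 1 and 2. The log2 values correlated across genes, which are not independent replicates, at r = 0.936 between the libraries labelled control and r = 0.941 between those labelled knockdown, against r = 0.789 to 0.898 for libraries with different labels.

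TFAP2C, the targeted gene (gene ID 100144525, chromosome 17, 57164400 to 57174923, Sscrofa11.1), stood at 14.7 and 7.78 FPKM under labelled controls 1 and 2. Under labelled knockdowns 1 and 2 it stood at 0.448 and 3.11 FPKM. The fold change as deposited was -2.27 on the log2(FPKM + 1) scale (SE 0.57), and it did not pass the threshold (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0745). The position of these values within the table does not match their scale. In the 35394 other rows the deposited coverage divided by FPKM was a single constant within a library wherever FPKM was above 0. Rows listed at 0 in a library, 12662 to 14428 of them, give no ratio there. The constant was 6.69, 7.03, 6.07 and 8.83 for labelled controls 1 and 2 and labelled knockdowns 1 and 2. In the TFAP2C row the same ratio was 6.07, 8.83, 6.69 and 7.03 in that order, so the values listed under each group carry the constants of the other group's libraries. TPM (transcripts scaled to a fixed library sum) divided by FPKM showed the same exchange. Placed in the libraries whose constants they carry, the TFAP2C values were 0.448 and 3.11 FPKM for the controls and 14.7 and 7.78 FPKM for the knockdowns, a fold change of 2.27 (limma, Benjamini-Hochberg adjusted p = 0.0745). If only this row was exchanged and the labels are right, TFAP2C RNA was not lower in the labelled knockdowns, and these data show no knockdown. Because the targeted gene does not check the labels, libraries are called labelled control and labelled knockdown throughout, and every direction below is labelled knockdown minus labelled control. Its relatives TFAP2A, TFAP2B, TFAP2D and TFAP2E were too low to test, and the highest value among them was 0.334 FPKM, for TFAP2A in labelled control 2.

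**Figure D1:**
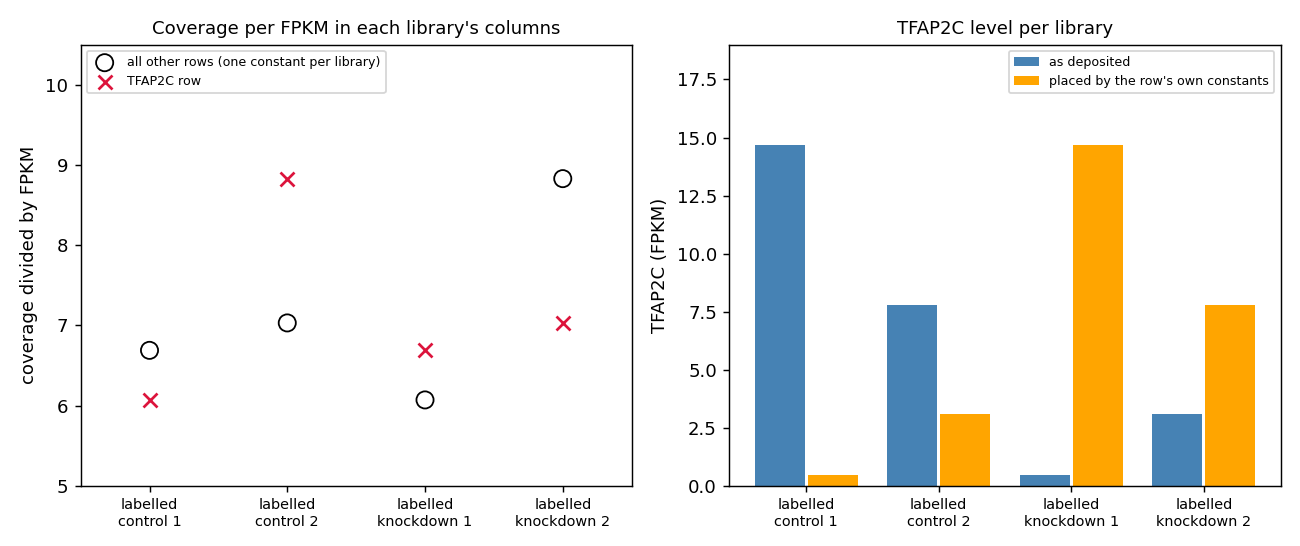
Left: deposited coverage divided by FPKM in the columns of each library, for the other rows with a value above 0 (circles, 1 constant per library) and for the TFAP2C row (crosses). Right: TFAP2C level in FPKM as deposited (blue) and placed by the row's own constants (orange). The crosses sit at 6.07 and 8.83 under the labelled controls and at 6.69 and 7.03 under the labelled knockdowns, the constants of the other group.

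The comparison of the groups asks which transcripts of the 4-cell embryo, those of epigenetic regulators among them, differ when TFAP2C is targeted. In the libraries labelled knockdown 24 of 57 cytosolic ribosomal protein genes, 6 of 24 genome activation genes with the homeobox gene ARGFX among them, and 7 of 40 oxidative phosphorylation genes rose, and none of these lists had a fall. Of 30 oocyte transcripts 5 fell and none rose, including WEE2 (an oocyte kinase that holds meiotic arrest), MOS (a kinase of meiotic metaphase arrest), H1FOO (the oocyte linker histone) and ZAR1L. These 4 lists passed with a preset inter-gene correlation, and each lost its call with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.80 to 0.81). The estimated form has only 2 residual degrees of freedom, so this loss does not measure correlation alone. The maintenance DNA methylation cofactor UHRF1 was lower, close to the threshold (limma, Benjamini-Hochberg adjusted p = 0.0473). It lost its call with a pseudocount of 0.1, after median-ratio scaling and with a minimum mean of 5 FPKM. The Polycomb genes EED and AEBP2 were higher. Neither the DNA methylation list nor the H3K27 list passed (camera with the preset correlation, Benjamini-Hochberg adjusted p = 0.86 and 0.83). Of 9850 genes tested, 503 were higher and 144 were lower in the libraries labelled knockdown (limma, Benjamini-Hochberg adjusted p under 0.05). All of these calls were at least 2-fold on the FPKM + 1 scale, with a median log2 fold change of 2.32 among the rises and -1.59 among the falls. The median over all tested genes was -0.13, and it became 0.006 after median-ratio scaling and -0.37 with TPM. Of the calls, 81 rises and 8 falls had a value of 0 in some library, and 134 rises and 34 falls were genes without a symbol. Without labelled knockdown 1 or without labelled knockdown 2 limma called 0 genes in either direction, though 891 and 1381 genes were higher and 828 and 1285 lower at an unadjusted p under 0.05. Without labelled control 1 it called 160 higher and 14 lower, without labelled control 2 it called 463 and 42, and with no filter on low values 0 and 0 (1930 and 1766 unadjusted). A pseudocount of 0.1 gave 312 higher and 62 lower, a minimum mean of 5 FPKM 320 and 124, median-ratio scaling 535 and 78, and transcript rows in place of gene sums 70 and 34.

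The 12 named genes with the largest rise had log2 fold changes of 4.26 to 6.15. TIMM8A, a chaperone of protein import into mitochondria (chromosome X, 82978128 to 82981038), went from 0.334 ± 0.198 FPKM (SD, n = 2) to 93.5 ± 11.9 (SD, n = 2). Its log2 fold change was 6.15 (SE 0.29, limma with Benjamini-Hochberg adjusted p = 0.0047). FABP5, a fatty acid binding protein (chromosome 4, 55277831 to 55282585), went from 3.01 ± 0.821 to 244 ± 108 FPKM (SD, n = 2 each). CRABP2, which binds retinoic acid (chromosome 4, 93388198 to 93393861), went from 0.365 ± 0.190 to 45.3 ± 2.63 FPKM. RSL24D1, a ribosome assembly factor (chromosome 1, 116612335 to 116629161), went from 3.92 ± 1.29 to 191 ± 54.6 FPKM. TFAM, which packages and transcribes mitochondrial DNA, stood at 0.754 and 13.3 FPKM in the labelled controls and 306 and 125 in the labelled knockdowns, a log2 fold change of 5.29 with an SE of 0.99. The splicing subunit SF3B5 had a log2 fold change of 5.24, the sterol carrier STARD4 4.95, SEM1 (a subunit of the proteasome lid) 4.54, and TOMM5 (outer membrane import) 4.52. The ribosomal protein genes RPS6 and RPL36AL stood at 4.43 and 4.42, and the proteasome subunit PSMB7 at 4.26.

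The 12 named falls were smaller in size than the 12 named rises, with log2 fold changes of -2.47 to -1.93. TNFAIP8 (chromosome 2, 123152349 to 123285154) went from 169 ± 11 to 29.7 ± 0.407 FPKM (SD, n = 2 each), a log2 fold change of -2.47 (SE 0.26, limma with Benjamini-Hochberg adjusted p = 0.0113). WEE2 (chromosome 18, 8171133 to 8196836) went from 718 ± 135 to 162 ± 13.5 FPKM, a log2 fold change of -2.13 (SE 0.28). H1FOO (chromosome 13, 68921491 to 68943061) went from 1157 ± 145 to 299 ± 66.4 FPKM and ZAR1L (chromosome 11, 8795478 to 8805876) from 188 ± 31.3 to 46.1 ± 15.8. STAT3, the transcription factor downstream of LIF and interleukin 6, went from 15.9 ± 5.38 to 3.11 ± 0.10 FPKM. The other named falls were ARF1, a small GTPase of the Golgi, at -2.22, CEP85 at -2.17, TRIM50 at -2.13, TMUB1 at -2.09, KAZN at -2.07, CACNA2D4 at -1.94 and BCAS4 at -1.93.

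**Figure D2:**
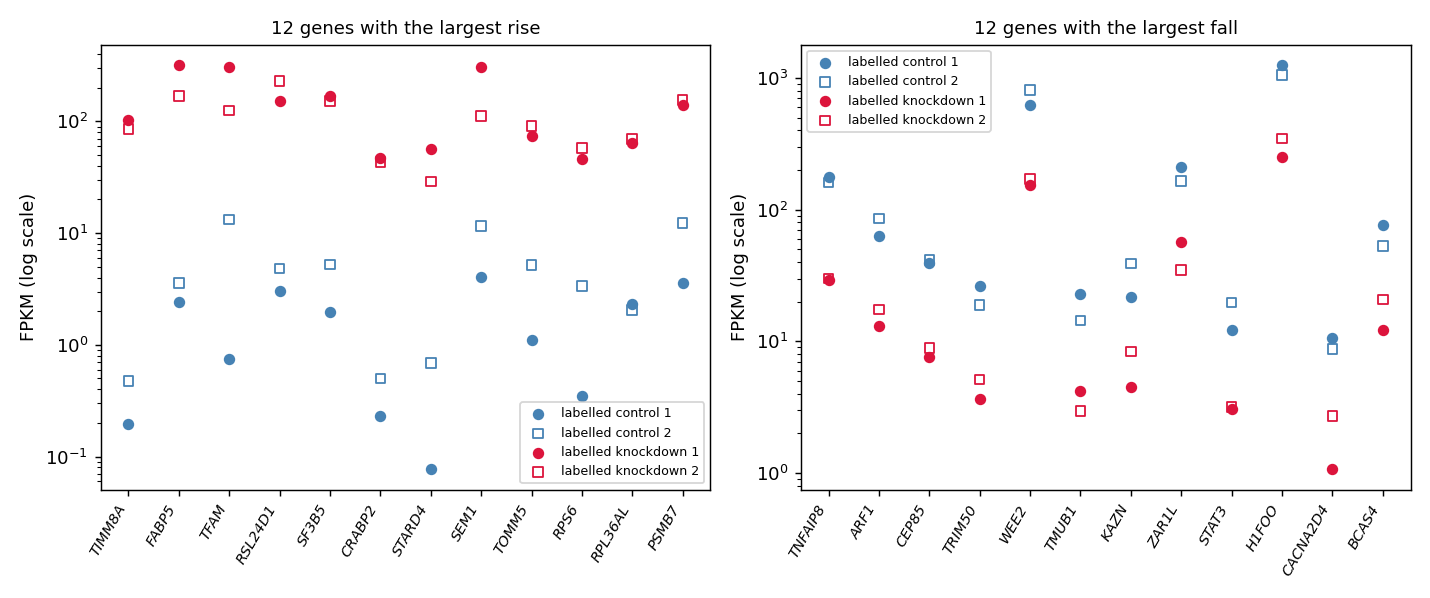
FPKM on a log axis in each of the 4 libraries for the 12 genes with the largest rise (left) and the 12 with the largest fall (right) under the naming rule; circles and squares are replicates 1 and 2, blue the libraries labelled control and red those labelled knockdown. For every gene shown, both red points lie on the same side of both blue points. TFAM ranges from 0.754 to 13.3 FPKM within the labelled controls.

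Cytosolic ribosomal protein genes were higher as a group. Of 57 tested, 24 rose and none fell (42 rose and none fell when adjusted over the list alone), and 52 had a positive fold change, with a median of 1.65. RPL18 went from 0.126 ± 0.0925 to 9.10 ± 1.20 FPKM (SD, n = 2 each) and RPL21 from 0.614 ± 0.166 to 18.6 ± 7.59. The RPL18 locus (chromosome 1, 84378453 to 84379052) is a short span that the data do not tell apart from a processed copy. RPL6 was listed at 0 and 0.776 FPKM in the labelled controls and at 22.5 and 32.7 in the labelled knockdowns. The list passed the threshold (camera with a preset correlation, Benjamini-Hochberg adjusted p = 1.7e-19), and camera gave an adjusted p = 0.80 with an estimated correlation. Ribosomal protein genes can share reads with near-identical processed copies, which was not measured here, so their levels are uncertain. In the file, 31 of 84 were listed at 0 in at least 1 library, and the housekeeping gene ACTB stood at only 0.695 to 1.56 FPKM. The 21 cumulus and granulosa markers summed to 23.3 and 16.6 FPKM in the labelled controls and to 23.2 and 17.7 in the labelled knockdowns, at most 1.16 times the labelled control mean. The 19 other than INHBA and FST, a subset chosen after the values were seen, summed to 1.67 to 1.90 times that mean, with single markers (TNFAIP6 and VIM in labelled knockdown 1, DCN in labelled knockdown 2) the largest parts of the difference.

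Genes of embryonic genome activation were also higher. Of 24 tested, 6 rose and none fell (8 and 0 adjusted over the list alone), and 20 had a positive fold change, with a median of 0.72. That median was 0.62 and 1.35 without labelled controls 1 and 2, 0.53 and 0.86 without labelled knockdowns 1 and 2, and 0.58 with TPM. The list passed with the preset correlation (camera, Benjamini-Hochberg adjusted p = 2.6e-04), while camera gave an adjusted p = 0.81 with an estimated correlation. ARGFX, a homeobox gene of early embryos (chromosome 13, 138927391 to 138928391), was listed at 0 and 0.0858 FPKM in the labelled controls and at 88.1 and 34.2 in the labelled knockdowns. The nucleolar methyltransferase FBL went from 0.344 ± 0.424 to 9.98 ± 2.01 FPKM (SD, n = 2 each), the translation initiation factor EIF3A from 1.28 ± 0.149 to 14.9 ± 4.55, and the splicing factor SRSF3 from 39.6 ± 0.923 to 108 ± 2.97. EIF1AX and NOP58, chosen for mention after their values were seen, had log2 fold changes of 1.68 and 2.99. In the same libraries the marker sum was at most 1.16 times the labelled control mean over all 21 cumulus and granulosa markers and 1.67 to 1.90 times over the 19 other than INHBA and FST, largely from TNFAIP6, VIM and DCN.

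Oocyte transcripts were lower as a group. Of 30 tested, 5 fell and none rose (10 fell and none rose when adjusted over the list alone), and 28 had a negative fold change, with a median of -0.67. Besides WEE2, H1FOO and ZAR1L, MOS (chromosome 4, 75739402 to 75741076) fell from 245 ± 5.74 to 65.3 ± 1.90 FPKM (SD, n = 2 each), and the oocyte importin KPNA7, chosen for mention after its value was seen, had a log2 fold change of -1.57. The list passed the threshold (camera with the preset correlation, Benjamini-Hochberg adjusted p = 4.5e-05), and camera gave an adjusted p = 0.80 with an estimated correlation. In the same libraries the marker sum was at most 1.16 times the labelled control mean over all 21 cumulus and granulosa markers and 1.67 to 1.90 times over the 19 other than INHBA and FST, largely from TNFAIP6, VIM and DCN. Genes of maternal mRNA decay did not move as a list in a single direction. Of 28 tested, only the CCR4-NOT subunit CNOT9 rose, by 1.80 on the log2 scale, and none fell (1 and 0 adjusted over the list alone), with a median of -0.23 (camera, Benjamini-Hochberg adjusted p = 0.95), or -0.025 without labelled knockdown 1 and -0.071 without labelled control 1.

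Of 40 nuclear-encoded oxidative phosphorylation genes tested, 7 rose and none fell (7 and 0 adjusted over the list alone), with a median of 0.35, or 0.15 without labelled control 2. NDUFB3, a subunit of complex I, went from 0.136 ± 0.0820 to 9.08 ± 2.88 FPKM (SD, n = 2 each). COX7A2, a subunit of cytochrome c oxidase, was listed at 2.70 and 0 FPKM in the labelled controls and at 67.9 and 79.5 in the labelled knockdowns. The list passed with the preset correlation (camera, Benjamini-Hochberg adjusted p = 0.0034) and gave an adjusted p = 0.81 with an estimated correlation. In the same libraries the marker sum was at most 1.16 times the labelled control mean over all 21 cumulus and granulosa markers and 1.67 to 1.90 times over the 19 other than INHBA and FST, largely from TNFAIP6, VIM and DCN. Among 13 genes encoded by the mitochondrial genome, 12 had a positive fold change and none passed the threshold (none adjusted over the list alone), with a median of 0.64. ATP6 stood at 33687 and 43659 FPKM in the labelled controls and at 112036 and 59065 in the labelled knockdowns. That list passed too (camera, Benjamini-Hochberg adjusted p = 0.011), with an adjusted p = 0.81 with an estimated correlation. It lost its call without labelled control 1 (median 0.56, camera with Benjamini-Hochberg adjusted p = 0.21) and without labelled knockdown 1 (median 0.32, adjusted p = 0.14), and its median was 0.97 without labelled knockdown 2. Quantile normalization and the absence of a filter also ended that call (camera, Benjamini-Hochberg adjusted p = 0.18 and 0.11). Of 34 proteasome subunit genes tested, PSMB7, PSMD6, PSMB4 and PSMA3 rose by 4.26, 2.80, 1.57 and 1.41 on the log2 scale and none fell (5 and 1 adjusted over the list alone). The proteasome list had a median of 0.16, or -0.206 with TPM, and missed the threshold (camera, Benjamini-Hochberg adjusted p = 0.073). It passed without labelled control 1 (median 0.45, camera with Benjamini-Hochberg adjusted p = 0.016), without labelled knockdown 1 (median 0.36, adjusted p = 0.048), and among genes above 0 in all 4 libraries (median 0.24, adjusted p = 0.036), and its median was 0.10 without labelled control 2 and 0.27 without labelled knockdown 2.

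**Figure D3:**
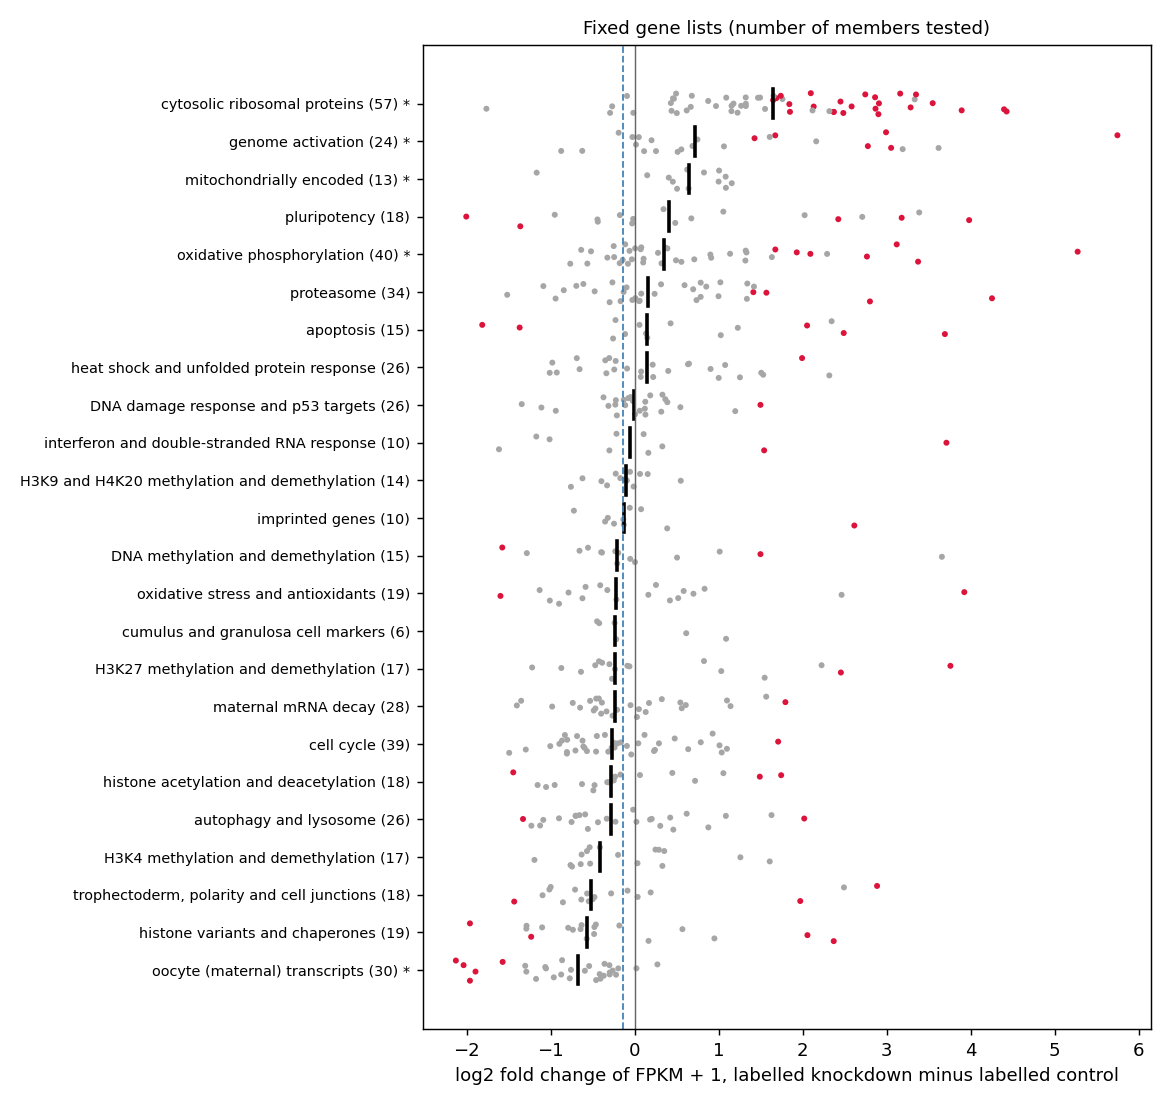
Log2 fold change of FPKM + 1, labelled knockdown minus labelled control, for each tested member (points; red past the gene threshold) of the 24 lists tested; black bars are list medians, the dashed line the median of all tested genes at -0.13, and an asterisk marks the 5 lists past the camera threshold with the preset correlation. The ribosomal list has the highest median, 1.65, and the oocyte list the lowest, -0.67.

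Among the genes that write and erase DNA methylation, UHRF1, which directs DNMT1 to replicated DNA (chromosome 2, 73898061 to 73937727), fell from 10.3 ± 2.72 to 2.77 ± 0.677 FPKM (SD, n = 2 each). GADD45A, a stress-induced gene linked to active demethylation and placed on the list for that, rose from 1.01 ± 0.00381 to 4.72 ± 0.958 FPKM. These were the only calls among 15 tested members (2 rose and 2 fell when adjusted over the list alone). The list as a whole, with a median of -0.21, a mean of 0.077 and a negative camera direction, did not pass (camera, Benjamini-Hochberg adjusted p = 0.86). Its median was -0.39 without labelled knockdown 2, -0.057 after median-ratio scaling and -0.48 with TPM. UHRF1 missed the threshold without labelled control 1 or 2 (limma, Benjamini-Hochberg adjusted p = 0.198 and 0.0713), with a pseudocount of 0.1 (0.0588), after median-ratio scaling (0.0564) and with a minimum mean of 5 FPKM (0.0559). GADD45A missed it without labelled control 1 or 2 (limma, Benjamini-Hochberg adjusted p = 0.161 and 0.125), with a pseudocount of 0.1 (0.0514) and with TPM (0.0629). None of the methyltransferases and dioxygenases fixed for mention passed the threshold (limma, Benjamini-Hochberg). The maintenance enzyme DNMT1 was abundant, at 2245 ± 18.8 against 1545 ± 318 FPKM, with a log2 fold change of -0.55 (95% interval -1.25 to 0.15). DNMT3A had a log2 fold change of -0.21 (interval -0.86 to 0.45) and DNMT3B one of -1.28 (interval -2.14 to -0.43, limma with Benjamini-Hochberg adjusted p = 0.087). TET1, TET2 and TET3 had log2 fold changes of 0.51, -0.23 and -0.66, each with an interval that includes 0. TDG, a glycosylase of active demethylation, was listed at 0 and 5.14 FPKM in the labelled controls and at 46.6 and 19.6 in the labelled knockdowns. It passed only without labelled control 2 among the libraries left out (limma, Benjamini-Hochberg adjusted p = 0.0052 against 0.069 with all libraries).

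Histone modifiers moved singly and not as lists in a single direction. Of 17 Polycomb and other H3K27 methylation genes tested, EED, the core subunit that reads H3K27 methylation (chromosome 9, 20123077 to 20158747), rose from 0.968 ± 0.450 to 10.4 ± 5.83 FPKM (SD, n = 2 each). AEBP2, an accessory subunit of Polycomb repressive complex 2 (chromosome 5, 53617362 to 53691487), rose from 0.233 ± 0.0559 to 16.2 ± 5.62 FPKM. None fell (3 rose and 1 fell when adjusted over the list alone), and the list had a median of -0.23, a mean of 0.41 and a positive camera direction (camera, Benjamini-Hochberg adjusted p = 0.83). That median was 0.032 without labelled control 1, -0.12 without labelled knockdown 1, -0.061 after median-ratio scaling and -0.44 with TPM. Of 17 H3K4 methylation genes none passed (none adjusted over the list alone), with a median of -0.41 (camera, Benjamini-Hochberg adjusted p = 0.83). The H3K4 median was -0.006 without labelled knockdown 1, -0.63 without labelled knockdown 2 and -0.26 without labelled control 1. The H3K4 demethylase KDM5B stood at 0.0578 and 0.176 FPKM in the labelled controls and at 3.71 and 1.46 in the labelled knockdowns, a log2 fold change of 1.61 (limma, Benjamini-Hochberg adjusted p = 0.069). Among genes above 0 in all 4 libraries KDM5B passed, as did RBBP5, a core subunit of H3K4 methyltransferase complexes with a log2 fold change of -1.19 (limma, Benjamini-Hochberg adjusted p = 0.0446 and 0.0469). Of 14 H3K9 and H4K20 methylation genes none passed (none adjusted over the list alone), with a median of -0.11 (camera, Benjamini-Hochberg adjusted p = 0.83), and the median was 0.027 after median-ratio scaling, -0.18 without labelled control 1 and -0.17 without labelled knockdown 1 or 2. Of 18 histone acetylation genes the deacetylases SIRT1 and HDAC2 rose, from 8.67 ± 0.578 to 31.7 ± 5.84 FPKM and from 18.3 ± 2.06 to 53.4 ± 8.91, and HDAC3 fell from 3.58 ± 0.466 to 0.683 ± 0.180. The SIRT1 rise lay on transcript NM_001145750.2, listed at 0 in both labelled controls and at 30.2 and 22.6 FPKM in the labelled knockdowns, while XM_021072203.1 stood at 9.08 and 7.97 against 4.32 and 4.52. Adjusted over the list alone 2 rose and 3 fell, and the list had a median of -0.28 (camera, Benjamini-Hochberg adjusted p = 0.83), or -0.16 without labelled knockdown 1. Of 19 histone variant and chaperone genes, H2AFZ rose from 172 ± 94.9 to 826 ± 0.341 FPKM and H3F3A, a gene for the H3.3 variant, rose by 2.06 on the log2 scale. H1FOO fell, and the chaperone ASF1B had a log2 fold change of -1.23. The counts were 3 and 4 adjusted over the list alone, and the list had a median of -0.57 (camera, Benjamini-Hochberg adjusted p = 0.22). With TPM the calls of SIRT1, HDAC2, H2AFZ, H3F3A and ASF1B ended (limma, Benjamini-Hochberg adjusted p = 0.0529, 0.0930, 0.0527, 0.0558 and 0.0536), and after median-ratio scaling those of HDAC3 and ASF1B (adjusted p = 0.0523 and 0.0648). Without labelled control 1 the calls of EED, SIRT1, HDAC2, HDAC3, H2AFZ, H3F3A, H1FOO and ASF1B ended too, and without labelled control 2 those of SIRT1, HDAC2, HDAC3 and ASF1B (limma, Benjamini-Hochberg adjusted p = 0.087, 0.141, 0.120 and 0.153). A pseudocount of 0.1 ended those of HDAC2, HDAC3, H2AFZ, H3F3A and ASF1B (adjusted p = 0.0535, 0.0604, 0.0507, 0.0600 and 0.0617), and limma without a trend that of ASF1B (0.0543).

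Lineage genes gave mixed directions. Of 18 pluripotency genes tested, 3 rose and 2 fell (5 and 2 adjusted over the list alone). DPPA2, which binds promoters of early embryonic genes, rose from 3.75 ± 2.57 to 68.8 ± 11.9 FPKM (SD, n = 2 each) and KLF4 from 5.96 ± 3.41 to 58.3 ± 3.98. The KLF4 rise lay on transcript XM_005660316.3, listed at 0 in both labelled controls, while NM_001031782.2 was listed at 0 in both labelled knockdowns. MYCN was listed at 0 and 1.20 FPKM in the labelled controls and at 8.23 and 5.90 in the labelled knockdowns. STAT3 fell, as did LIN28A, chosen for mention after its value was seen, by 1.36 on the log2 scale. The list had a median of 0.41 (camera, Benjamini-Hochberg adjusted p = 0.21), and without labelled control 2 it passed (median 0.55, adjusted p = 0.039). Its median was 0.27 without labelled control 1, 0.20 without labelled knockdown 1 and 0.90 without labelled knockdown 2. POU5F1 (OCT4) did not pass, at 11.7 ± 0.787 against 8.34 ± 0.0351 FPKM. NANOG (chromosome 1, 169064134 to 169065292, a short span that the data do not tell apart from a processed copy) stood at 0.0392 and 16.5 FPKM in the labelled controls. It stood at 34.7 and 20.9 in the labelled knockdowns. Labelled control 2 decided its call, since NANOG did not pass with all libraries (limma, Benjamini-Hochberg adjusted p = 0.22) and passed without that library (log2 fold change 4.75, adjusted p = 0.0034). SOX2 and CDX2 did not exceed 0.213 FPKM in any library and were not tested. Of 18 trophectoderm, polarity and junction genes, ATP1B3, a sodium pump subunit, rose from 1.92 ± 0.589 to 20.5 ± 3.99 FPKM, DSC2, a desmosomal cadherin, was listed at 0 and 0.181 against 4.72 and 2.18 FPKM, and EZR, a cortical linker protein, fell from 19.8 ± 1.00 to 6.81 ± 1.67. The counts were 3 and 1 adjusted over the list alone, with a list median of -0.52 (camera, Benjamini-Hochberg adjusted p = 0.53), or -0.30 without labelled knockdown 1. Of 10 imprinted genes only UBE3A rose, by 2.62 on the log2 scale, and none fell (1 and 0 adjusted over the list alone). That list had a median of -0.13, a mean of 0.11 and a positive camera direction (camera, Benjamini-Hochberg adjusted p = 0.997), and its median was 0.126 without labelled knockdown 1, -0.071 and -0.25 without labelled controls 1 and 2, and 0.028 after median-ratio scaling.

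Stress and death genes did not pass as lists in a single direction either. Of 15 apoptosis genes, the mitochondrial antagonist of inhibitor proteins DIABLO rose from 0.112 ± 0.0251 to 5.37 ± 1.73 FPKM (SD, n = 2 each). The survival gene BCL2L1 fell from 76.6 ± 2.45 to 21.1 ± 0.615 FPKM. BID was listed at 0 FPKM in both libraries labelled control and at 12.9 and 11 in those labelled knockdown, and BAD, chosen for mention after its value was seen, rose by 2.05 on the log2 scale. The counts were 3 higher and 2 lower (the same numbers adjusted over the list alone), with a median of 0.15 (camera, Benjamini-Hochberg adjusted p = 0.21) that became -0.131 with TPM, 0.24 without labelled control 1, and 0.38 and 0.36 without labelled knockdowns 1 and 2. Of 26 autophagy and lysosome genes, ATG4B was listed at 0 in both libraries labelled control and at 3.54 and 2.62 FPKM in those labelled knockdown, and BECN1 fell by 1.33 on the log2 scale. The counts were 2 and 1 adjusted over the list alone, with a median of -0.28 (camera, Benjamini-Hochberg adjusted p = 0.83), or -0.10 without labelled control 2 and -0.18 without labelled knockdown 2. Of 19 oxidative stress genes, the peroxiredoxin PRDX6 stood at 5.84 and 30.7 against 283 and 175 FPKM and passed as a rise, and the catalase gene CAT fell from 32.9 ± 3.24 to 10.4 ± 3.24. The counts were 2 and 1 adjusted over the list alone, with a list median of -0.22, a mean of 0.12 and a negative camera direction (camera, Benjamini-Hochberg adjusted p = 0.95). That median was -0.37 without labelled control 1, -0.013 without labelled knockdown 2, -0.052 after median-ratio scaling and -0.55 with TPM. Of 26 DNA damage and p53 target genes only GADD45A passed, and none did adjusted over the list alone, with a median of -0.007 whose sign differed from its mean of 0.0066 and its camera direction, and which was 0.141 after median-ratio scaling (camera, Benjamini-Hochberg adjusted p = 0.91). It was -0.073 and -0.013 without labelled controls 1 and 2, and 0.132 and -0.067 without labelled knockdowns 1 and 2. Of 26 heat shock and unfolded protein genes only HSPA5, the chaperone of the endoplasmic reticulum, passed, rising from 14.4 ± 1.13 to 60.4 ± 0.202 FPKM (1 rose and none fell adjusted over the list alone). That list had a median of 0.15, which became -0.127 with TPM (camera, Benjamini-Hochberg adjusted p = 0.31), 0.035 without labelled control 2, and 0.031 and 0.021 without labelled knockdowns 1 and 2. Of 10 interferon and double-stranded RNA response genes, OAS1 rose from 0.445 ± 0.582 to 17.2 ± 0.0164 FPKM, TLR3 was listed at 0 and 0.355 against 1.95 and 2.91 FPKM, and none fell. The counts were 2 and 2 adjusted over the list alone, with a list median of -0.05, or 0.105 after median-ratio scaling, a mean of 0.15 and a positive camera direction (camera, Benjamini-Hochberg adjusted p = 0.95). The interferon median was -0.13 and -0.029 without labelled controls 1 and 2, and -0.60 and 0.0038 without labelled knockdowns 1 and 2. Of 39 cell cycle genes only the cyclin CCND2 rose, by 1.71 on the log2 scale, and none fell (1 and 0 adjusted over the list alone), with a median of -0.27 (camera, Benjamini-Hochberg adjusted p = 0.55), or -0.16 without labelled knockdown 1.

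Of 6 tested cumulus and granulosa markers, the cells that surround the oocyte, none passed (none adjusted over the list alone), with a median of -0.23, a mean of 0.063 and a negative camera direction (camera, Benjamini-Hochberg adjusted p = 0.997). That median was 0.20 without labelled control 1 or labelled control 2 and -0.068 without labelled knockdown 1. The markers with the highest levels were INHBA, at 7.07 ± 1.12 against 5.05 ± 1.07 FPKM (SD, n = 2 each), and FST, at 6.61 ± 4.55 against 4.22 ± 1.78. VIM stood at 0.0403 and 0.325 FPKM in the labelled controls and at 2.81 and 0.556 in the labelled knockdowns. TNFAIP6 stood at 0.0864 and 0.352 FPKM in the labelled controls and at 4.32 and 0.250 in the labelled knockdowns, and DCN at 0.931 and 0.607 against 0.559 and 3.67. All 21 markers summed to 23.3 and 16.6 FPKM in the labelled controls and to 23.2 and 17.7 in the labelled knockdowns. The 19 other than INHBA and FST, a subset chosen after the values were seen, summed to 5.64 and 6.92 FPKM in the labelled controls and to 11.96 and 10.48 in the labelled knockdowns. Of the blood cell and sperm markers only CD3E and ODF2 were abundant enough to test, and neither passed. CD3E stood at 2.05 ± 1.05 against 0.840 ± 0.859 FPKM and ODF2 at 1.61 ± 0.514 against 1.25 ± 0.0890, and that list and the TFAP2 family had too few tested members for a list test.

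Of the 70 called genes under the naming rule, many lay close to the threshold. With no filter all 70 lost their call, as did the 67 and 68 of them that were tested without labelled knockdowns 1 and 2, since limma then called no gene. Without labelled control 1 limma lost 38 of the 70, WEE2, H1FOO, ZAR1L, MOS, BCL2L1 and HSPA5 among them, and without labelled control 2 it lost 24, STAT3, MOS and BCL2L1 among them. A pseudocount of 0.1 ended 25 calls, including those of TFAM, KAZN, PRDX6, MYCN, DSC2 and COX7A2. TPM ended 13, those of GADD45A, SIRT1, HDAC2, H2AFZ, H3F3A, ASF1B, MYCN, EZR, SRSF3, CNOT9, TLR3, PSMB4 and PSMA3. Median-ratio scaling ended 8, including those of KAZN, UHRF1, HDAC3, ASF1B, BECN1, CAT and EZR. Quantile normalization ended those of CCND2, TLR3 and PSMA3, limma without a trend that of ASF1B, and a minimum mean of 5 FPKM that of UHRF1. TIMM8A, FABP5, CRABP2, RSL24D1, DPPA2, KLF4, ARGFX, AEBP2, FBL and EIF3A kept their calls under each of these settings except the loss of a library labelled knockdown and the absence of a filter.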

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

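TPM, genes above 0 in all libraries, transcript rows and the move of the TFAP2C values were chosen after seeing the data. Where a library was left out, limma assumes that the lone library varies like the other group. A count test, planned only for a table of counts, was not run. The replicate numbers were not taken to pair the libraries, as the labels state no pairing and there are 2 pairs (the correlation across genes of replicate 1 minus replicate 2 between the groups was -0.14); with the replicate block 125 genes were higher and 8 lower (124 and 8 of them shared with the 503 and 144), and 42 of the 70 called genes under the naming rule missed the threshold. Leaving out a library gave between 0 and 463 higher genes and between 0 and 42 lower ones, with the smallest adjusted p at 0.124 and 0.0769 in the fits without labelled knockdowns 1 and 2 (limma, Benjamini-Hochberg). A pseudocount of 0.1 gave 312 and 62, no filter 0 and 0 of 22933 genes tested (smallest adjusted p 0.0816), a minimum of 5 FPKM 320 higher genes (fewer genes tested), median-ratio scaling 535 and 78, and transcript rows 70 and 34; apart from the smaller number of libraries or genes, the cause was not tested. Quantile normalization gave 482 and 169, limma without a trend 495 and 137, TPM 384 and 163, genes above 0 in all libraries 536 and 211, and the fold threshold 503 and 144. TFAP2C ran from -3.02 to -1.51 over the other settings, with adjusted p from 0.0514 to 0.27 (limma, Benjamini-Hochberg), and turned to 2.27 when placed by its constants, by construction. Lists past the threshold went from 5 to 0 with an estimated correlation in camera (0 lists at an unadjusted p under 0.05), on 2 residual degrees of freedom. They also went to 0 with the directional form of fry (8 lists unadjusted, smallest adjusted p 0.079). The mixed form of fry asks whether members changed in either direction. It passed every tested list except H3K4, H3K9 and H4K20, imprinted genes, cumulus markers and mitochondrially encoded genes (fry, Benjamini-Hochberg adjusted p = 0.053, 0.20, 0.058, 0.86 and 0.20). Over 14 settings the ribosomal, activation, oocyte and oxidative phosphorylation lists kept direction and call, with medians of 1.15 to 2.85, 0.53 to 1.35, -0.90 to -0.52 and 0.11 to 0.51. The mitochondrially encoded list lost its call in 4 of them, without labelled control 1, without labelled knockdown 1, with no filter and after quantile normalization, with a median of 0.32 to 0.97 over the 14. Values of genes and lists not past the threshold turned sign as follows. Leaving out each library gave -1.10 to 0.204 for FST, -0.40 to 0.0023 for ODF2, -0.27 to 0.032 for the H3K27 list, -0.073 to 0.132 for DNA damage, -0.25 to 0.126 for imprinted genes, -0.60 to 0.0038 for interferon and -0.17 to 0.205 for cumulus markers. After median-ratio scaling the H3K9 and H4K20 list was 0.027, DNA damage 0.141, imprinted genes 0.028 and interferon 0.105. DNA damage was 0.014 after quantile normalization and 0.0057 with no filter, where cumulus markers were 0.042. With TPM apoptosis was -0.131, heat shock -0.127 and the proteasome -0.206. Of the alternatives for named genes, 1162 kept direction and side of the threshold, 360 lost the threshold, 12 gained it and 2 turned. With about 6 to 9 aligned gigabases a library, depth was not compared with the spread.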

Other observations

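The grouping by symbol, the 2 tests on the TFAP2C row and the tests of summed somatic markers, the last of them after the value of the one before, were chosen after the values were seen. Genes were grouped by the start of their symbol, and 43 families with at least 15 tested members were compared. Of 42 genes whose symbols start with EIF, 9 rose and none fell, with a median log2 fold change of 0.53 (camera with the preset correlation, Benjamini-Hochberg adjusted p = 6.1e-04; adjusted p = 0.86 with an estimated correlation). The family of translation initiation factors overlaps the genome activation list, which holds EIF1AX and EIF3A among others. The genes that rose were EIF1AD, EIF1AX, EIF2B2, EIF2S1, EIF3A, EIF3G, EIF3H, EIF4G1 and EIF6. Of 36 mitochondrial ribosomal protein genes starting with MRPL, 6 rose and none fell, with a median of 0.41, and that family missed the threshold (camera, Benjamini-Hochberg adjusted p = 0.052). Among symbols that start with RPL 16 of 31 rose, and among those that start with RPS 10 of 26. These groups largely repeat the fixed ribosomal list and also hold genes outside it, such as kinases of the RPS6K series.

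The values in the TFAP2C row carry the constants of the other group's libraries, so that the gene is lower in the libraries labelled knockdown as deposited and higher in them by its own constants. Rounding is argued against by the other rows, of which 0 failed the match, though a row listed at 0 in a library gives no ratio to check there. An exchange of the group labels for every other gene remains open and cannot be told apart from an exchange of values within this row. Placed by its constants TFAP2C had a log2 fold change of 2.27, which such an exchange of labels needs, but the same value follows if only this row was altered. In that second case the data show no lowering of TFAP2C RNA in the libraries labelled knockdown. If the group labels of the other rows were exchanged, every direction in the text would turn, and no other row checks the labels.

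The second pattern is that 24 of 57 ribosomal protein genes and 6 of 24 activation genes rose while 5 of 30 oocyte transcripts fell in the libraries labelled knockdown, in lists that lost their call with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.80, 0.81 and 0.80). Scaling by a single factor per library is argued against, since the oocyte median was still -0.52 after median-ratio scaling while the ribosomal median was 1.74. Such a factor moves all lists alike. Technical differences that act on some transcripts more than on others were not tested. A candidate explanation is that the embryos behind the libraries had advanced to different degrees, with or without an effect of the knockdown, which is the difference the design names and was not tested apart. The test set before the values were seen asked whether the libraries labelled control differ along the same axis. The oocyte median of labelled control 2 minus labelled control 1 was -0.013, with ribosomal and activation medians of 0.21 and 0.31. Labelled knockdown 2 minus 1 gave 0.058, -0.33 and -0.22, opposite signs with an oocyte median also within 0.1 of 0. The labelled control medians did not meet the bound for the explanation (opposite signs, each beyond 0.1). The bound against the explanation was a shared sign or values within 0.1 of 0. The oocyte median lay within 0.1 of 0 and the ribosomal and activation medians did not. The test as run could only favour the explanation or stay undecided, so nothing is concluded from it. The bounds were also wrong, since a difference between groups needs none within the single pair of labelled controls. Timing cannot be told apart from the knockdown or from exchanged labels. RNA of somatic cells also stays open: a first test asked whether VIM and collagen genes stayed under 1 FPKM and was undecided (VIM 2.81 in labelled knockdown 1), the sum over 21 cumulus and granulosa markers was at most 1.16 times the labelled control mean, and without INHBA and FST, which carry that sum, the other 19 summed to 11.96 and 10.48 FPKM in the labelled knockdowns against 5.64 and 6.92, at least 1.67 times the mean, between the bounds set at 1 and 2, with markers near the floor.

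The third pattern is a change of the dominant transcript of a gene between the labelled groups. Of 1976 genes with several transcript rows, a mean of at least 5 FPKM and at least 1 FPKM in every library, 1253 had the same most abundant transcript in all 4 libraries and 69 had one transcript in both libraries labelled control and another in both labelled knockdown. The other splits of the 4 libraries gave 48 and 45 genes, and 3 splits are too few for a share under 0.05. In KLF4, an example chosen after its values were seen, a curated RefSeq transcript stood at 3.56 and 8.37 FPKM in the labelled controls and a predicted one at 61.1 and 55.5 in the labelled knockdowns, each listed at 0 in the other group. For PSMA5 the levels were 49.5 and 26.4 FPKM on one transcript in the labelled controls and 70.7 and 49.8 on another in the labelled knockdowns, so transcript assignment may follow how StringTie divided reads as well as the embryos, and the 69 genes do not separate these.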
